A study of Mus musculus with 4 samples.

How the data were processed

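Gene expression was measured on 4 one-colour oligonucleotide arrays, 1 per cell population, from total RNA of mouse hematopoietic cells on the C57BL/6 background. Per the labels' protocols, RNA was purified on RNeasy columns, amplified as amino-allyl RNA with the Amino Allyl MessageAmp II kit, coupled to Cy5 and fragmented by the procedure of Toray Industries, the array's maker. The 4 populations were LKS stem and progenitor cells sorted from normal fetal liver, fetal liver LKS cells infected with an Id3 retrovirus, the same cells infected with a mock retrovirus, and lineage-negative bone marrow cells of E2A-/- mice. Per the labels, infected cells were sorted on the human CD25 marker 2 days after infection and cultured for 30 days on TSt-4 stromal cells with SCF, IL-7 and Flt3-L. The E2A-/- cells were cultured in the same way for at least 2 months, after magnetic enrichment. Origin, enrichment and time in culture therefore differ along with the genotype in every comparison that holds the E2A-/- library. The labels name no infection for the E2A-/- cells, so retroviral infection differs as well from both infected cultures. Each population has 1 array, so no comparison has a replicate check.

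The deposited table holds 1 linear probe intensity per probe and array for 23473 probes. The authors' scaling is visible in the values only: the median of the listed intensities is 20.0 on every array (19.99 to 20.0). The scanner, the background correction and the rule by which a probe was left without a value are not given in the sources used here. Between 5.58% (LKS) and 8.83% (mock) of probes had no value on an array, and the lowest listed intensity was 1.06 for LKS, 1.23 for the Id3-labelled library, 1.15 for E2A-/- and 1.57 for mock. Because these medians were taken over different sets of listed probes, they do not place the same probes at the same level. Intensities were therefore converted to log2 and each array was centred on its median over the 20153 probes listed on all 4 arrays. Centring moved the mock array by 0.096 on the log2 scale and the others by -0.056 (LKS), -0.021 (Id3-labelled) and -0.018 (E2A-/-).

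Gene names came from the platform annotation, which gave 1 symbol for 16631 probes, several symbols for 0 probes and none for 6842 probes, which were not used here. Of the symbols, 12622 were current in the GRCm38.p6 gene table, 3947 were updated through a synonym that belonged to 1 gene, 59 had ambiguous synonyms and 3 had no match, and these last groups kept the array's name. No build is named for the array, so no coordinates are given. The probes named 16390 genes, of which 229 had more than 1 probe, and each gene was represented by its brightest probe among those listed on the most arrays. Probe sequences were not used here, so cross-hybridisation between close paralogs such as Vpreb1 and Vpreb2 cannot be excluded.

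A comparison used genes listed in both samples whose mean log2 level was at or above the 25th percentile of all probes listed in both. Differences were called at 2-fold, and no p-value was computed, because 1 array per group leaves no spread between replicates. As the available measure of error, the log2 differences of the 2 brightest probes of the same gene were compared, which gave an SD per probe between 0.47 and 0.76 on the log2 scale. This SD also holds real differences between transcripts of a gene. Where the brighter probe differed by 2-fold, the second had the same sign in 12 of 16 genes for the Id3-labelled library minus mock. The counts were 17 of 23 for E2A-/- minus mock and 6 of 9 for the Id3-labelled library minus E2A-/-. Against LKS they were 14 of 17 (Id3-labelled), 13 of 16 (E2A-/-) and 18 of 20 (mock). Simulated arrays with that SD, on which 200 genes were changed, were passed through the same steps. For the Id3-labelled library against mock (11332 genes passing the filter), 87% of 100 genes changed by 3 log2 units and 64% of 100 genes changed by 1.5 log2 units were called at 2-fold, while 25 of the 200 changed genes fell under the filter on dim probes. Of the unchanged genes in that simulation 14.5% (1621 genes) passed 2-fold, 1.85% passed 3-fold and 1 gene passed 8-fold. Counts at 8-fold are therefore given beside counts at 2-fold. The simulation used normal noise with 1 SD for all genes, so its count at 8-fold depends on that shape.

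A total of 14 gene lists was fixed before the data were examined, with 336 different members, of which 295 had a probe. For each list the median log2 difference is given with its exact binomial (sign) 95% interval over members, which treats genes as the sampled units and says nothing about replicate cultures. The median was also placed among 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays. Named genes were fixed by rule before the data were examined: the 8 (comparisons with mock) or 4 (other comparisons) most different named genes on each side among genes at or above the median level, up to 4 members per list described, and the targeted genes Tcf3 and Id3. For comparisons sharing the mock array, unchanged groups were simulated 100 times against 1 common array with a noise SD of 0.51 per array. Alternatives planned in advance were values as deposited, quantile normalization, no filter or a filter at the 50th percentile, the mean of a gene's probes, a pseudocount of 16, a 3-fold threshold, unmatched random lists and Pearson correlation. A common floor of 6.13 under dim and unlisted probes was added after seeing the data. It was an alternative for list medians, and folds of single genes are given with listed readings under it set to it. Some list members were named after their folds with this floor were seen. The computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.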

Results

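The arrays compared 4 populations of mouse hematopoietic cells: LKS cells sorted from fetal liver, which hold the stem and multipotent progenitor cells, and 3 populations kept on TSt-4 stromal cells. These were fetal liver LKS cells transduced with Id3, an inhibitor that binds E proteins and keeps them from DNA (here the Id3-labelled library), fetal liver LKS cells carrying a mock vector, which the labels call control pro-B cells, and bone marrow progenitors lacking E2A, the E protein encoded by Tcf3. Each population was measured once. The arrays listed an intensity for 22164 probes in LKS, 21868 in the Id3-labelled library, 21400 in mock and 21871 in E2A-/-, and the number of arrays limits the precision of every value below. Across probes, the Id3-labelled and E2A-/- libraries were the most alike of the 6 pairs (Spearman 0.963), and E2A-/- and mock the least alike (0.927). The LKS library correlated with the cultured libraries between 0.928 (mock) and 0.933 (Id3-labelled). Genes are not independent replicates, and these coefficients describe 4 arrays. Readings under an intensity of 6.13 after centring, the highest of the arrays' 25th percentiles, were not shown to be above background. Folds of single genes below are ratios of centred readings in which such readings were set to 6.13, a common floor chosen after the data were seen, unless a fold is given as read. The floor is not a measured detection limit, so a fold that rests on it is uncertain. It entered 46 of the 64 differences of genes named by size, and these genes were chosen on the values as read, so that their choice and order are uncertain too. List medians and counts of genes used the values as read. A pseudocount of 16 moved 58 of these 64 differences, taken as read, by more than the SD between probes, and none changed direction (0).

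The targeted genes were examined first as a check of the labels. The brighter of 2 Tcf3 probes read 14.1 in E2A-/-, against 829 in mock, 411 in LKS and 326 in the Id3-labelled library, so that it was 63.7-fold lower in E2A-/- than in mock. The dimmer probe was also lowest in E2A-/-, at 4.48, with 18.6 in mock. The single Id3 probe went against the label. It read 64.8 in the Id3-labelled library and 806 in mock, a 13.5-fold lower value in the library said to carry the Id3 vector, and it read 179 in LKS and 30.8 in E2A-/-. Whether this probe lies in the transduced sequence was not determined, and a probe outside it would not check the label. All directions for this library below rest on the label as given.

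**Figure D1:**
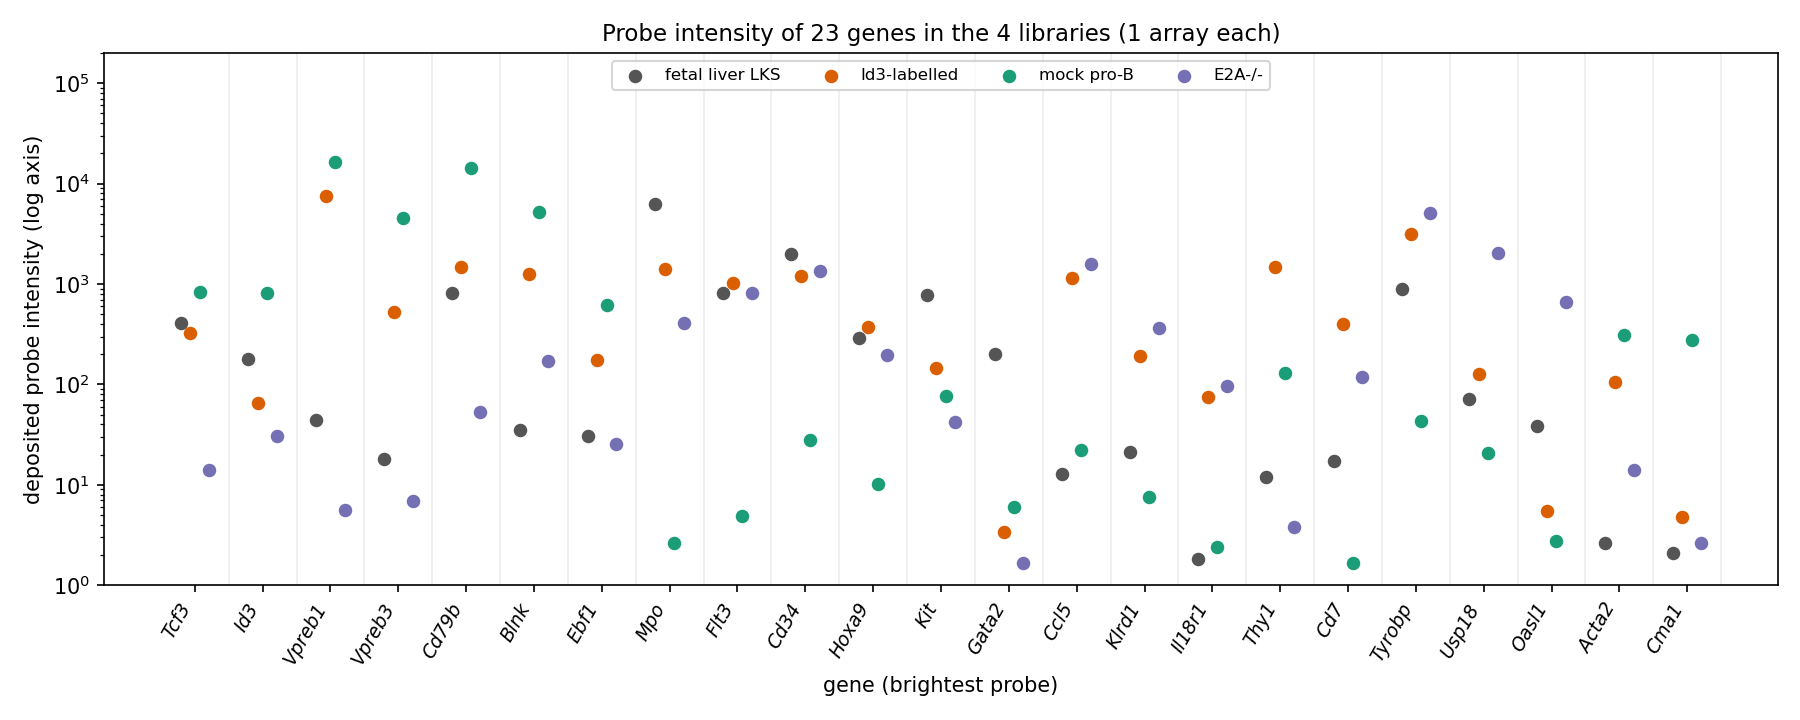
Deposited probe intensity on a log axis (y) for the genes named on the x axis in the 4 libraries, 1 point per array, with colours for fetal liver LKS, Id3-labelled, mock pro-B and E2A-/- cells. Vpreb1 spans from 5.57 in E2A-/- to 16417 in mock, with 7495 in the Id3-labelled library, and Mpo lies at 6317 in LKS and 2.65 in mock.

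The comparison of the Id3-labelled library with mock asked what Id3 does to the same fetal liver cells over the same culture. Genes of the B lineage were lower in the Id3-labelled library, and some genes of early progenitors and of natural killer and innate lymphoid cells were higher. Of 27 measured B lineage genes 21 were at least 2-fold lower and 0 higher, with a median of -2.68 on the log2 scale (95% interval -3.23 to -1.68). The largest differences were in Ms4a1 (CD20, 39.3-fold lower), Blk, a B cell Src kinase (36.7-fold lower), Bst1 (19.4-fold lower) and Fcrla (19.4-fold lower). The surrogate light chain genes Vpreb1 and Vpreb2, whose probes may cross-react, differed less, with 7495 and 5687 in the Id3-labelled library against 16417 and 16857 in mock. Ebf1, a transcription factor that starts the B cell program, read 175 against 613, and Pax5, which maintains it, read 5.13 against 32.4. These last 4 genes were named after their values were seen.

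Of 30 stem and multipotent progenitor genes with a probe 22 were listed on both arrays and passed the filter on dim probes. Of these 10 were at least 2-fold higher, 11 within 2-fold and 1 lower in the Id3-labelled library, with a median of 0.79 (0.14 to 2.90). The higher genes included the cytokine receptor gene Flt3 (163-fold higher), Hoxa5 (40.7-fold), Cd34 (39.1-fold) and Hoxa9 (33.4-fold). The lower gene, named after its value was seen, was Prdm16, at 1.41 against 29.4. Members left out included Gata2 (3.36 against 5.99) and Tie1 (2.38 against 5.98), dim on both arrays. With dim and unlisted members set to the common floor the median was lower, inside its interval. Of 27 myeloid genes with a probe 15 were listed on both arrays and passed the filter on dim probes, of which 8 were at least 2-fold higher and 1 lower, with a median of 1.15 (0.23 to 5.45) that fell to 0.068 with dim and unlisted members set to the common floor. Mpo, the granule enzyme myeloperoxidase, read 1402 against 2.65, a difference of 488-fold as read and 225-fold with the floor. The adaptor genes Tyrobp and Fcer1g were 67.6-fold and 46.6-fold higher, and the granule protease gene Prtn3 was 27.5-fold higher. Of 21 natural killer and innate lymphoid genes with a probe 12 were listed on both arrays and passed the filter on dim probes. Of these 8 were at least 2-fold higher, 4 were within 2-fold and 0 were lower, with a median of 3.21 (0.66 to 5.08). Members left out included Ncr1 (4.73 against 5.43) and Prf1 (3.22 against 3.23), but also Xcl1, at 65.8 and unlisted in mock. With dim and unlisted members set to the common floor the median was lower, inside its interval. Ccl5, a chemokine, was 46.9-fold higher, Nfil3, a factor needed for natural killer and innate lymphoid cells, 35.2-fold, Tox 23.6-fold and Klrd1 23.4-fold. Id2, also on this list, read 413 against 66.9. The 4 members within 2-fold, named after their values were seen, were Tbx21, Eomes, Gzmb and Il12rb2. In LKS, Ccl5, Nfil3, Tox and Klrd1 read 12.8, 250, 84.1 and 21.1, against 22.4, 20.7, 4 and 7.62 in mock. The mock reading was thus below that of LKS for Nfil3, Tox and Klrd1. The random-list percentile of the progenitor, myeloid and innate lymphoid medians was 100, and that of the B lineage list was 0. These percentiles used only members that passed the filter. The interferon response and the immediate early and stress lists also lay at 100. The stromal feeder and the mast, basophil and eosinophil lists also lay at 0, so extreme percentiles were not particular to the lists above.

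Some T lineage genes were also higher in the Id3-labelled library, in 7 of 17 measured, with 2 lower and a median of 0.34 whose interval included 0 (-0.17 to 3.38). With the filter at the 50th percentile this median was 3.47, over fewer genes. Cd7 was 64.1-fold, Cd27 27.2-fold and Cd28 24.4-fold higher, whereas Hes1, a Notch target, was 12.3-fold lower, and the T cell receptor component genes Cd3e, Cd3d and Cd3g stayed below an intensity of 15 in all 4 libraries (looked up after the other values were seen). Interferon response genes were higher in 7 of 13 with 0 lower (median 1.13, 0.81 to 2.45), with Irf7 5.84-fold and Usp18 5.67-fold higher. Immediate early and stress genes were higher in 9 of 17 with 0 lower (median 1.20, 0.17 to 2.02), led by Fos (89.6-fold) and Ier3 (22.6-fold). Cell cycle genes had a median of -0.51 (-0.71 to -0.25), with 3 of 30 at least 2-fold lower, among them Rrm2 (2.93-fold) and Kif11 (2.78-fold), when the median of all genes in this comparison was -0.095. Lists of other cells differed as well. Stromal feeder genes were lower in the Id3-labelled library in 16 of 19 (median -1.51, -1.92 to -1.07), including Fn1 (5.53-fold) and Bgn (4.36-fold), and mast, basophil and eosinophil genes in 6 of 10 (median -1.08, -5.71 to 0.26), including the mast cell protease genes Cma1 (48.6-fold) and Cpa3 (45.5-fold). The lower B lineage values in the Id3-labelled library thus went together with lower stromal values, while the interval of the mast, basophil and eosinophil list included 0. With a pseudocount of 16 the stromal feeder median was -0.98. Dendritic and antigen presentation genes had 3 of 11 higher (median 0.33, -0.78 to 3.50), with H2-Aa 11.3-fold and Cd86 7.36-fold higher. The medians of the erythroid and megakaryocyte list (0.0066), the fetal program list (0.32) and the E protein and Id list (-0.48) had intervals that included 0, although Igf2 was 24.3-fold and the neighbouring imprinted RNA H19 15.0-fold lower.

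Over all 11341 genes, 778 were at least 2-fold higher and 934 lower in the Id3-labelled library, and 121 were at least 8-fold higher and 92 lower. With the values as deposited 934 were at least 2-fold higher and 757 lower, so the larger side turned with the scaling. In a simulation with the disagreement between probes of a gene as noise (SD 0.68), 1621 unchanged genes passed 2-fold and 1 passed 8-fold. This noise was estimated from 117 genes and also holds real differences between transcripts. For E2A-/- minus mock such noise gave more 2-fold calls than the data, so it is no fitted baseline for either count. Without replicates, the count at 2-fold cannot be read as a count of changed genes. The 8 named genes with the largest higher values as read were Mpo, Cd7, Flt3, the chemokine gene Ccl3 (166-fold), Hspb3 (59.3-fold), the chemokine receptor gene Ccr2 (92.6-fold), Il31ra (47.4-fold) and Flt1 (47.6-fold). The 8 with the largest lower values as read were the fatty acid transporter gene Cd36 (74.9-fold), Gldc (69.1-fold), Prkcb, a protein kinase C (92.7-fold), Ptgr1 (74.4-fold), Ms4a1, Blk, Dpp4 (64.0-fold) and Cma1. For 12 of these 16 genes the dimmer reading was under the common floor. In each of the 6 comparisons at least 1 of the counts at 2-fold moved by over 1.5 times with a pseudocount of 16.

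**Figure D2:**
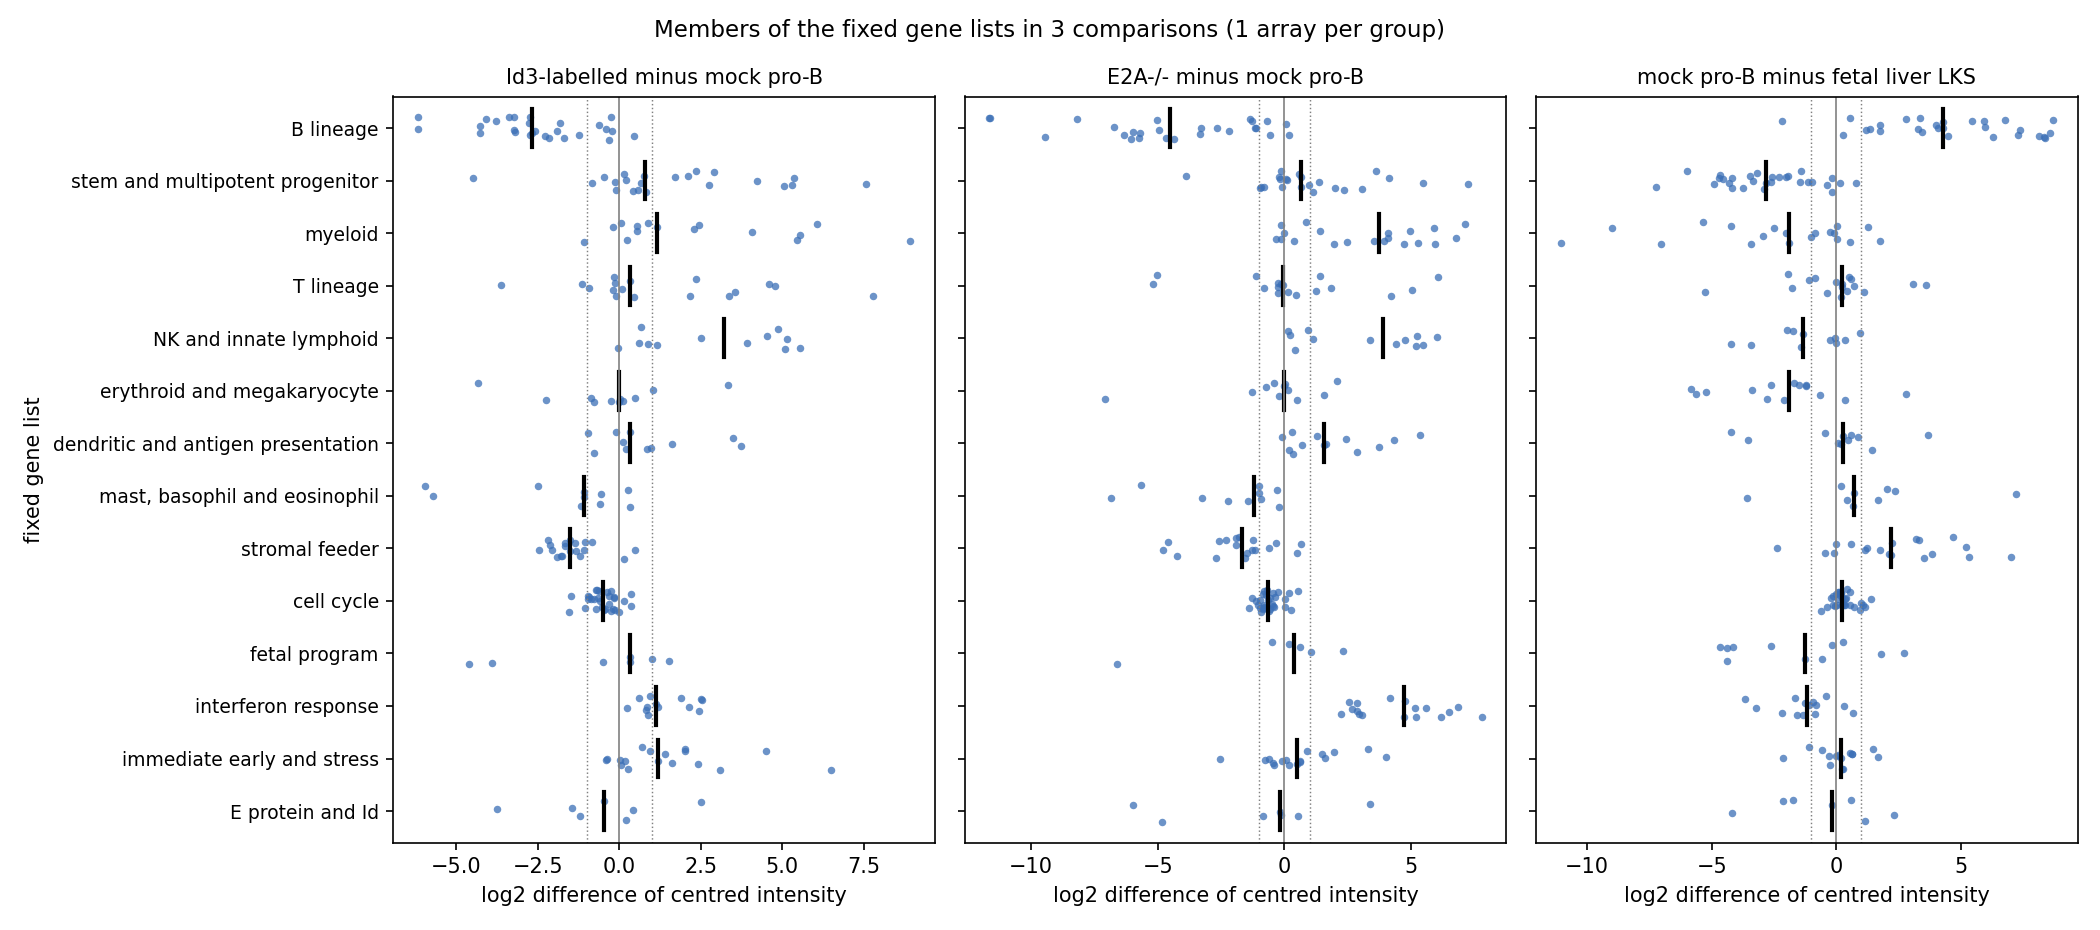
Log2 difference of centred intensity (x axis) for each measured member of the 14 fixed lists (y axis) in 3 comparisons, 1 point per gene and 1 array per group. Black bars are list medians and dotted lines mark 2-fold, and the B lineage median lies at -2.68, -4.52 and 4.29 from left to right.

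The comparison of E2A-/- cells with mock addressed the loss of E2A itself, with bone marrow origin, enrichment, retroviral infection of mock only and longer culture as further differences. B lineage genes were lower than in mock by larger amounts than in the Id3-labelled library. Many myeloid, innate lymphoid and dendritic genes and the measured interferon response genes were higher. Of 26 measured B lineage genes 22 were at least 2-fold lower and 0 higher, with a median of -4.52 (-5.99 to -1.38). Vpreb2 and Vpreb1 read 5.66 and 5.57 in E2A-/-, 3224-fold and 3190-fold lower as read and 2937-fold and 2860-fold lower with the floor. Vpreb3, at 6.93 in E2A-/-, was 708-fold lower and Cd79b, a signalling chain of the B cell receptor, 291-fold. Pou2af1 and Lef1, both named after their values were seen, had no listed value in E2A-/- and read 1080 and 173 in mock. Of 27 myeloid genes with a probe 20 were listed on both arrays and passed the filter on dim probes. Of these 14 were at least 2-fold higher and 0 lower, with a median of 3.75 (0.87 to 4.96). They were led by Tyrobp (109-fold), Mpo (65.2-fold), Fcgr3 (62.6-fold) and Fcer1g (59.8-fold). Of 21 natural killer and innate lymphoid genes with a probe 12 were listed on both arrays and passed the filter. Of these 8 were higher and 0 lower (median 3.91, 0.43 to 5.23), led by Ccl5 (65.1-fold), Klrd1 (44.1-fold) and Nfil3 (36.7-fold). With dim and unlisted members set to the common floor, this median and the myeloid median were both lower, inside their intervals.

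Of 18 interferon response genes with a probe 17 were listed on both arrays and passed the filter on dim probes. All 17 were at least 2-fold higher in E2A-/- than in mock, with a median of 4.71 (2.89 to 5.58). Ifit1, the member left out, was dim in both E2A-/- (2.76) and mock (2.93). Oasl1 and the chemokine gene Cxcl10 were each 106-fold higher, Usp18 90.5-fold and Oas2 47.8-fold. Dendritic and antigen presentation genes were higher in 8 of 13 with 0 lower (median 1.58, 0.31 to 3.75), with Cd86 22.5-fold and the class II gene H2-Aa 20.3-fold higher. Stem and multipotent progenitor genes were higher in 9 of 23 and lower in 1 (median 0.65, -0.13 to 2.00), with Flt3 132-fold and Cd34 44.2-fold higher. The T lineage list had 6 of 17 higher and 3 lower (median -0.072, -0.27 to 1.41), with Cd28 32.9-fold and Cd7 19.2-fold higher and Hes1 28.9-fold and Thy1 22.6-fold lower. Immediate early and stress genes had a median of 0.49 (-0.40 to 1.49). Stromal feeder genes were lower in 14 of 18 (median -1.67, -2.57 to -1.14), mast, basophil and eosinophil genes in 6 of 10 (median -1.21, -5.65 to -0.30), and cell cycle genes in 4 of 30 (median -0.66, -0.81 to -0.45). With a pseudocount of 16 the stromal feeder median was -0.94, and after quantile normalization the cell cycle median was -0.42. The erythroid and megakaryocyte (-0.013), fetal program (0.40) and E protein and Id (-0.18) medians had intervals that included 0, with Igf2 82.1-fold lower and Id2 10.6-fold higher.

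Over all 11348 genes, 958 were at least 2-fold higher and 904 lower in E2A-/-, and 203 were at least 8-fold higher and 153 lower. The simulation of unchanged genes for this comparison (SD 0.76) passed 2123 genes at 2-fold and 2 at 8-fold. At 2-fold this was more than the 1862 genes called in the data, so the simulated noise does not describe these arrays well. The 8 named genes with the largest higher values as read were Ly86 (362-fold), Ccr2 (257-fold), Ccl3 (237-fold), Oasl1, the Fc receptor gene Fcgr1 (66.0-fold), Gpr183 (99.7-fold), Flt3 and Mpo. For 13 of the 16 named genes the dimmer reading was under the common floor. The 8 with the largest lower values as read were Vpreb2, Vpreb1, the sodium pump subunit gene Atp1b1 (629-fold), Vpreb3, Ly6d (368-fold), Syce2 (151-fold), Ttll11 (72.1-fold) and Cd79b.

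Both comparisons used the same mock array. Among 11082 genes measured in both, 529 were at least 2-fold higher than mock in both cultures, which was 71.9% of the 736 higher in the Id3-labelled library, and 567 were lower in both. Independent lists of these sizes would share 57.5 higher and 72.3 lower genes, and simulated unchanged groups against 1 common array shared 270.3 higher and 272 lower. That simulation called 909 genes higher in the first group, against 736 observed. Its noise thus gave more 2-fold calls than the data, and its shared counts are no fitted baseline. Across genes, the 2 sets of log2 differences correlated with Pearson 0.793 and Spearman 0.748, against 0.499 and 0.482 in the simulation. The simulated correlations follow from equal noise on a shared array, whatever its SD. They hold no estimate from these data. Their covariance was 0.81 against a simulated 0.26, a difference of 0.55. With 1 mock array the controls could not be split, so part of the excess may come from that array. A total of 16 genes was at least 2-fold higher than mock in one culture and lower in the other. The 4 with the largest gaps, which were chosen after their values were seen, were Thy1 (1464 in the Id3-labelled library, 130 in mock, 3.81 in E2A-/-), the lysosomal enzyme gene Hexa (10.2, 70.2 and 874), Xlr3b (241, 23.04 and 4.38) and the immediate early gene Egr1 (351, 37.8 and 6.95).

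**Figure D3:**
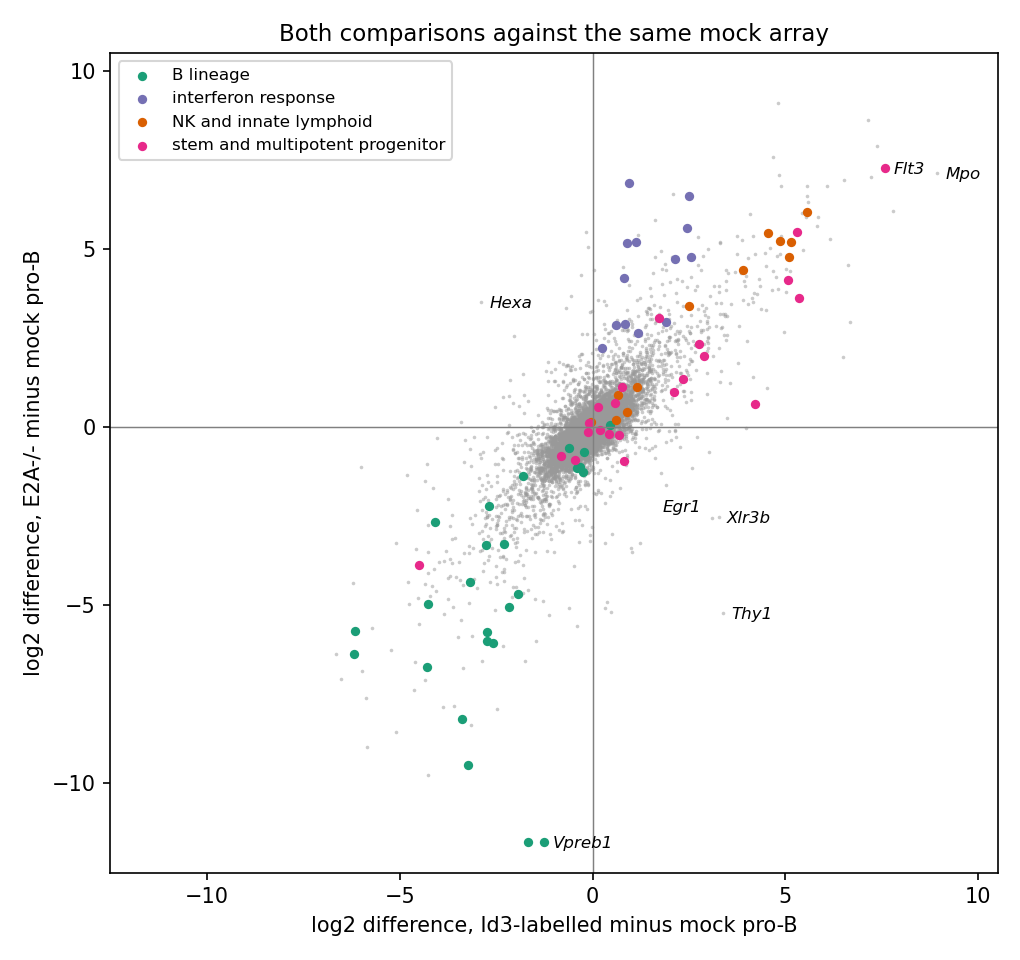
Log2 difference to mock in the Id3-labelled library (x axis) and in E2A-/- cells (y axis), 1 grey point per gene, with members of 4 lists in colour and 1 array per group. Interferon response genes lie above the main cloud and Vpreb1 far below it, at -11.64 on the y axis.

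Set directly against each other, the Id3-labelled library had higher B lineage values than E2A-/- and lower interferon response and myeloid values. Of 22 B lineage genes 12 were at least 2-fold higher and 1 lower (median 1.09, 0.45 to 3.24), with Vpreb1 1204-fold, Vpreb2 914-fold, Vpreb3 75.6-fold and Cd79b 27.9-fold higher. All 17 interferon response genes that passed the filter on dim probes were at least 2-fold lower (median -3.13, -4.28 to -2.22), led by Oasl1 (106-fold), Cxcl10 (60.4-fold) and Ifit3 (34.8-fold). The median was -2.07 with a pseudocount of 16. Ifit1, left out by the filter, read 2.94 in the Id3-labelled library and 2.76 in E2A-/-. Myeloid genes were lower in 10 of 19 and higher in 1 (median -1.06, -1.94 to -0.17), led by Mmp8 (41.8-fold), Cd14 (14.9-fold), Csf3r (5.24-fold) and Adgre1 (4.89-fold). Dendritic and antigen presentation genes were lower in 4 of 13 with 0 higher (median -0.83, -2.08 to -0.013). Immediate early and stress genes were higher in 6 of 17 and lower in 1 (median 0.63, 0.12 to 1.20), with Egr1 50.4-fold and Fos 22.7-fold higher. T lineage genes were higher in 5 of 18 and lower in 1 (median 0.38, -0.056 to 1.41), with Thy1 235-fold higher, and stem and multipotent progenitor genes were higher in 5 of 24 and lower in 1 (median 0.29, -0.11 to 0.91), with Hoxa10 11.9-fold higher. None of 30 cell cycle genes (0) differed by 2-fold (median 0.10, -0.033 to 0.22). Natural killer and innate lymphoid genes had 2 higher and 2 lower of 16 (median -0.21, -0.89 to 0.39). The erythroid and megakaryocyte median was 0.28 (0.020 to 1.63), and the stromal feeder (0.28), mast, basophil and eosinophil (0.14), fetal program (-0.15) and E protein and Id (0.38) medians had intervals that included 0. Over 11513 genes, 57 were at least 8-fold higher and 74 lower, and 380 and 587 passed 2-fold. Among named genes the largest differences as read were Vpreb1, Vpreb2, Thy1 and Vpreb3 on the higher side and Oasl1, Hexa (85.6-fold), Cxcl10 and Ifit3 on the lower side.

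Against the uncultured fetal liver LKS cells, the mock library had higher B lineage values and lower progenitor and erythroid values. Of 28 B lineage genes 25 were at least 2-fold higher and 1 lower (median 4.29, 3.28 to 6.28), led by Vpreb1 (413-fold), Vpreb2 (378-fold), Vpreb3 (280-fold), Pou2af1, a B cell coactivator (188-fold), and Bst1 (184-fold). Of 29 stem and multipotent progenitor genes 23 were lower and 0 higher (median -2.83, -4.18 to -1.44), led by Flt3 (128-fold), Cd34 (63.2-fold), Gata2 (30.3-fold) and Hoxa5 (26.3-fold). Myeloid genes were lower in 11 of 19 and higher in 2 (median -1.91, with an interval of -4.22 to 0.024 that included 0), with Mpo 990-fold and Prtn3 324-fold lower. Erythroid and megakaryocyte genes were lower in 11 of 14 and higher in 1 (median -1.90, -5.24 to -0.65), with Nfe2 49.9-fold and the erythropoietin receptor gene Epor 28.5-fold lower. Interferon response genes were lower in 8 of 14 with 0 higher (median -1.18, -2.17 to -0.43). Stromal feeder genes were higher in 14 of 19 and lower in 1 (median 2.20, 0.58 to 3.83), with Acta2 53.7-fold, Bgn 22.6-fold and Cxcl12 14.2-fold higher, and mast, basophil and eosinophil genes were higher in 4 of 9 and lower in 1 (median 0.70, 0.18 to 2.37), with Cma1 48.6-fold higher. Natural killer and innate lymphoid genes had a median of -1.32 (-3.44 to 0.33), the fetal program list -1.27 (-4.38 to 1.80), cell cycle 0.23 (0.084 to 0.37), T lineage 0.22 (-0.84 to 0.59), dendritic and antigen presentation 0.25 (-3.56 to 1.43), immediate early and stress 0.20 (-0.31 to 0.62), and E protein and Id -0.19 (-4.18 to 2.32). The median of all genes here was 0.12. The cell cycle median was 0.077 as deposited and 0.033 after quantile normalization, and the T lineage median was -1.08 with the filter at the 50th percentile. Over 11421 genes, 157 were at least 8-fold higher and 173 lower, and 881 and 1031 passed 2-fold. Besides Mpo, Prtn3 and Flt3, the lower named gene chosen by size as read was the endothelial receptor gene Adgrl4 (139-fold).

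The Id3-labelled library had higher B lineage, innate lymphoid and immediate early values than LKS and lower erythroid and fetal program values. Of 23 B lineage genes 14 were at least 2-fold higher and 2 lower (median 1.35, 0.89 to 4.04), with Vpreb1 174-fold, Vpreb2 117-fold, the adaptor gene Blnk 36.7-fold and Vpreb3 29.9-fold higher. Stem and multipotent progenitor genes were lower in 13 of 28 and higher in 1 (median -0.84, -2.40 to 0.019). Prdm16 was 36.3-fold, Gata2 31.7-fold and Tie1 24.7-fold lower, while Flt3 read 1016 against 815, Cd34 1196 against 1984 and Hoxa9 373 against 290, genes named here after their values were seen. Erythroid and megakaryocyte genes were lower in 11 of 15 and higher in 1 (median -2.31, -3.56 to -0.74), led by Car2 (56.4-fold) and Pf4 (16.8-fold). Myeloid genes were lower in 12 of 21 and higher in 5 (median -1.04, -2.14 to 0.61), with Csf3r 58.4-fold and Ctsg 28.8-fold lower. Natural killer and innate lymphoid genes were higher in 7 of 14 with 0 lower (median 1.31, 0.41 to 4.17), with Ccl5 91.2-fold and Il18r1 12.1-fold higher, and immediate early and stress genes in 11 of 17 with 0 lower (median 1.21, 0.69 to 2.64). T lineage genes were higher in 7 of 20 and lower in 2 (median 0.45, -0.51 to 1.40), with Thy1 126-fold, Cd7 23.9-fold and Il2ra 19.1-fold higher, and a median of 2.33 with the filter at the 50th percentile. Fetal program genes were lower in 6 of 10 with 0 higher (median -1.14, -5.55 to -0.24), with Cdkn1c 33.8-fold and Igf2bp1 33.3-fold lower. Stromal feeder genes had 7 of 17 higher and 3 lower (median 0.52, -0.10 to 1.94), with Acta2 16.9-fold higher. The cell cycle median was -0.27 (-0.36 to -0.062), and the dendritic and antigen presentation (0.22), interferon response (0.33), mast, basophil and eosinophil (-0.38) and E protein and Id (-0.30) medians had intervals that included 0. Over 11598 genes, 118 were at least 8-fold higher and 205 lower, and 825 and 1003 passed 2-fold. Vpreb1, Thy1, Vpreb2 and Hspb3 (59.3-fold) were the largest higher and Csf3r, Ldhb (75.3-fold), Trf (52.5-fold) and Rps4l (104-fold) the largest lower named genes as read.

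The E2A-/- cells did not show the higher B lineage values that both fetal liver cultures showed over LKS: of 20 genes 3 were at least 2-fold higher and 6 lower (median -0.054, -1.34 to 0.24), with Cd72 16.7-fold higher and Cd79b 14.9-fold lower. Interferon response genes were higher in 16 of 17 (median 3.41, 1.92 to 4.13), led by Cxcl10 (85.8-fold) and Mx1 (44.8-fold). Natural killer and innate lymphoid genes were higher in 8 of 14 with 0 lower (median 1.71, 0.37 to 4.98), with Ccl5 127-fold higher, and dendritic and antigen presentation genes in 7 of 13 with 1 lower (median 1.13, 0.49 to 3.68), with Cd74 70.4-fold higher. Myeloid genes split, with 10 of 25 higher and 9 lower (median 0.40, -1.91 to 2.39): Mmp8 was 41.8-fold and Fcgr3 15.5-fold higher, and Ctsg 32.2-fold and Prtn3 16.5-fold lower. Stem and multipotent progenitor genes were lower in 16 of 28 with 0 higher (median -1.29, -1.84 to -0.52), with Prdm16 36.3-fold and Gata2 31.7-fold lower. Erythroid and megakaryocyte genes were lower in 11 of 14 and higher in 1 (median -2.74, -4.07 to -0.38), and fetal program genes in 6 of 10 with 1 higher (median -1.42, -5.79 to 0.059). The E protein and Id list had a median of -1.62 (-4.83 to 1.66), with Tcf3 28.4-fold lower. The cell cycle median was -0.28 (-0.44 to -0.13) and the mast, basophil and eosinophil median -0.30 (-3.60 to -0.020), while the T lineage (-0.079), stromal feeder (0.20) and immediate early and stress (0.63) medians had intervals that included 0. With the filter at the 50th percentile the T lineage median was 1.93, and with the common floor the mast, basophil and eosinophil median was 0. Over 11603 genes, 154 were at least 8-fold higher and 227 lower, and 926 and 896 passed 2-fold. The largest named differences as read were Ccl2 (119-fold), Ccl5, Atf3 (45.8-fold) and Pmaip1 (107-fold) on the higher side and Syce2 (431-fold), Klk8 (159-fold), Car2 (329-fold) and Xlr3b (111-fold) on the lower side.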

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

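With 1 array per group, no library could be left out, and no paired analysis was possible because the groups share no replicate numbers beyond a single array each. A choice of scaling (values as deposited or quantile normalization) kept all 12 counts at 2-fold within 1.5 times and no list median, named gene or targeted gene turned its direction under any alternative run where its interval excluded 0. As deposited, the median of all genes moved from -0.095 to 0.022 for the Id3-labelled library minus mock and from 0.12 to -0.036 for mock minus LKS, and the share of higher calls from 45.4% to 55.2% and from 46.1% to 36.1%. Counts depended on the filter, the pseudocount and the threshold. A 3-fold threshold gave 370 higher and 406 lower (Id3-labelled minus mock), 562 and 446 (E2A-/- minus mock), 184 and 281 (Id3-labelled minus E2A-/-), 381 and 554 (Id3-labelled minus LKS), 474 and 532 (E2A-/- minus LKS) and 427 and 560 (mock minus LKS). A pseudocount of 16 gave 501 and 477, 544 lower only, 187 and 342, 480 and 565, 581 and 531, and 519 and 618 in that order, where E2A-/- minus mock moved by over 1.5 times on the lower side only. A filter at the 50th percentile gave 583 lower, 593 lower, 213 higher and 365 lower, 538 lower, 473 lower, and 577 higher and 607 lower in the same order. Without a filter, 1412 were lower in E2A-/- than in mock, 574 were higher in the Id3-labelled library than in E2A-/-, and 1384 were higher in mock than in LKS, and the Id3-labelled library had 1400 lower than mock. The overlap of the 2 comparisons with mock was 342 higher and 325 lower with the pseudocount and 344 lower at the 50th percentile. Under the alternatives 565 list medians stayed inside their interval and 12 did not, and of the 64 named-gene differences 58 moved by more than the SD between probes with the pseudocount and 29 with the common floor. With the pseudocount, the stromal feeder median was -0.98 (Id3-labelled minus mock) and -0.94 (E2A-/- minus mock), and the interferon response median -2.07 (Id3-labelled minus E2A-/-). At the 50th percentile the T lineage median was 3.47 (Id3-labelled minus mock), 2.33 and 1.93 (Id3-labelled and E2A-/- minus LKS) and -1.08 (mock minus LKS), over fewer genes. The cell cycle median was -0.42 after quantile normalization (E2A-/- minus mock), and 0.077 as deposited and 0.033 after quantile normalization (mock minus LKS). With the common floor, added after seeing the data, the myeloid median was 0.068 (Id3-labelled minus mock) and the mast, basophil and eosinophil median 0 (E2A-/- minus LKS). Other medians were lower with this floor but stayed inside wide intervals, so staying inside does not make them stable. These included the natural killer and innate lymphoid medians of both cultures minus mock. The myeloid median (E2A-/- minus mock) and the progenitor median (Id3-labelled minus mock) were lower too. Medians and means differed in sign for the erythroid (0.0066 and -0.32) and fetal program (0.32 and -0.83) lists in the Id3-labelled library minus mock, the T lineage and fetal program lists in E2A-/- minus mock, the fetal program list in the Id3-labelled library minus E2A-/-, the T lineage list in E2A-/- minus LKS, and the T lineage and dendritic lists in mock minus LKS. Signal limits the folds of dim probes: the 25th percentile of the listed intensities lay between 5.01 (Id3-labelled) and 5.74 (mock). The causes of these changes were not tested.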

Other observations

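Gene families defined by their symbols were examined after the main results were seen, and some of their members, such as Ms4a1 and Hoxa10, were also on fixed lists. Chemokine ligands were higher in E2A-/- than in LKS in 8 of 17 genes with 0 lower (median log2 difference 0.76, 95% interval 0.023 to 5.29), and 7 of 20 were lower and 2 higher in the Id3-labelled library than in E2A-/- (median -0.69, -1.27 to -0.040). In the Id3-labelled library minus mock, 3 of 19 were higher and 6 lower (median -0.20, -1.46 to 0.79). Ccl3 was 166-fold and Ccl4 28.6-fold higher there, as was Ccl5 of the natural killer and innate lymphoid list (46.9-fold), and Cxcl1 10.9-fold and Ccl7 7.71-fold lower, with readings under the common floor set to it. Ccl2 read 3.19 in LKS and 306, 778 and 737 in the Id3-labelled, mock and E2A-/- cultures. Of 8 Ms4a genes 4 were at least 2-fold higher and 1 lower in E2A-/- than in mock (median 0.93, -6.35 to 5.82), with Ms4a6b at 506 against 8.29 and Ms4a1 at 2.99 against 226. In the Id3-labelled library minus E2A-/-, 4 of 6 were lower and 0 higher (median -3.44, -5.18 to 0.078). Among Hox genes, Hoxa10 read 336 in the Id3-labelled library, 90.9 in LKS, 28.3 in E2A-/- and 16.7 in mock. Of 52 cytosolic ribosomal protein genes 2 were at least 2-fold higher and 1 lower in mock than in LKS, with a median of 0.45 (0.38 to 0.54). Their median was -0.37 in the Id3-labelled library minus mock and -0.46 in E2A-/- minus mock. In the comparisons without mock it lay between 0.0045 and 0.11, so the shift went with the mock array. Ifnb1, the interferon beta gene, read 30.1 in E2A-/- and between 5.58 and 11.4 in the other libraries. All tests in the next 3 paragraphs were chosen after their results were seen.

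The Id3 probe was lower in the library labelled as Id3-transduced than in mock (64.8 against 806). If the 2 libraries had been exchanged, the cells titled control pro-B would hold the lower B lineage values. The list's median was -2.68 (-3.23 to -1.68) in the Id3-labelled library minus mock. This argues against an exchange only if pro-B cells hold the higher values, as their title implies. The same median is the main result of this comparison, so it is no independent check of the labels. A candidate explanation is that the probe reads only the cell's own Id3, whose level goes with E2A activity: the probe was also lower in E2A-/- than in mock, by -4.82 on the log2 scale. Both differences rest on the mock array, in which stromal genes were also higher, so the source of the Id3 reading in mock was not settled. Against the uncultured LKS cells the probe was lower too, 2.69-fold in the Id3-labelled library and 5.65-fold in E2A-/-. The low reading in the Id3-labelled library thus does not depend on the mock array alone. The position of the probe relative to the transduced sequence and a loss of vector expression over 30 days stay open.

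Stromal genes were higher in mock than in the other libraries, with 14 of 22 genes listed on all 4 arrays highest there. Another scaling does not remove this. As deposited or after quantile normalization, the median for the Id3-labelled library minus mock was -1.40 at its nearest to 0. With a pseudocount of 16 that median was -0.98. Carried-over TSt-4 feeder cells may account for the higher stromal values in mock: the list's median was 2.20 in mock minus the uncultured LKS cells, and the labels give no sort after culture. A profile of TSt-4 cells was not analysed here. Expression of these genes by the blood cells of that culture stays open, and so does the source of H19 (2958 in mock, 214 in the Id3-labelled library, 497 in LKS) and of Cma1.

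Interferon response genes were highest in E2A-/- in 17 of 18 genes listed on all 4 arrays, and by at least 2-fold in 16. Scaling of the arrays does not account for it. As deposited or after quantile normalization, the median for the Id3-labelled library minus E2A-/- was -3.13 at its nearest to 0. With a pseudocount of 16 that median was -2.07. More mature myeloid cells in the E2A-/- culture cannot be told apart from a response of the progenitors themselves, because the myeloid list was also lower in the Id3-labelled library (median -1.06) and 1 bulk array does not say which cells hold the transcripts. Bone marrow origin, enrichment, a culture of at least 2 months, the lack of a named infection and the genotype differ together in this library and were not separated.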
